A study of Drosophila melanogaster with 102 samples.

How the data were processed

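Gene expression was measured by RNA-seq of total RNA from whole flies of strain w1118. Per the labels' protocols, RNA was extracted with Qiazol and a column kit with DNase treatment. The 102 libraries were grouped by generation, maternal diet, sex and day as the labels give them. The number of flies per library and the strandedness are not given in the sources used here.

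The authors deposited counts per gene, 1 table for mothers and 1 for progeny, with 14312 FlyBase gene identifiers. Per the submitters' processing notes, build BDGP6, kallisto (version not given), R 4.2.0 and DESeq2 1.36.0 were used. The notes give no role for each tool. All deposited counts are whole numbers (0 values are not whole), so they were tested as counts without rounding. How these genes were selected is not given in the sources used here. Symbols came from an Ensembl annotation of the reference, build BDGP6.54, with 10 identifiers left without a symbol, and coordinates are those of that annotation only. Every column was matched to a sample by its label. Kallisto shares reads among transcripts by likelihood, so counts of near-identical paralogs (lysozymes, Jonah proteases, maltases, Bomanins, diptericins) are uncertain, as are those of overlapping genes.

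From these counts, R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 computed all other values. Genes with low counts were removed by filterByExpr with a minimum count of 10 and a minimum total of 15. Libraries were scaled by TMM, and groups were compared by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Each fit held the 3 diet groups of mothers, or of progeny of the same sex and day. Differences between sexes, and dependence on the day, were tested as interaction terms in fits over the groups concerned. Ageing was compared among CD progeny. CPM per library used the TMM-scaled totals, and log2 CPM a prior count of 1. The 33 comparisons were HFD against CD, HSD against CD and HSD against HFD in mothers and in the 6 strata of sex and day, the sex differences, ageing in CD progeny and the day dependence.

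The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Of 41 gene lists, 40 had genes here. A list was tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether its genes move on balance 1 way without a comparison to other genes. Over 1240 list tests, 514 passed camera with the preset correlation, and 6 of these passed with an estimated correlation, 501 with median-of-ratios size factors and 113 by fry. The 6 are the mitochondrially encoded transcripts and adult fat body in day 10 sons (HFD against CD and HSD against HFD) and cytochrome P450s, muscle, adult fat body and cuticle proteins in ageing CD sons. Lists of ovary, testis, accessory gland, muscle, neuronal and gut genes serve also as markers of tissue share in whole flies. The testis list holds a widely expressed tubulin.

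The rule for named genes takes, for each diet against CD, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap and whose mean is 1 CPM or more. To these it adds the 5 smallest adjusted p and up to 4 members past the threshold of lists that passed their test or had at least 3 such members, and the 3 smallest p where no gene passed. Other comparisons take 4 rises and 4 falls. Antimicrobial peptides, Bomanins, the label-check genes (yolk proteins and seminal fluid proteins) and genes named in another comparison could be given anywhere, and fewer genes were used where space was short.

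The fitting and calling of genes were tested on simulated counts with 200 changed genes, and the list test on simulated raised and unchanged lists. The library checks, thinning, control splits and permutation scores were not tested in this way. Simulated genes were drawn independently of each other, so the simulation does not show how the list test behaves on correlated genes. For HFD against CD in mothers, 47.8, 80.6 and 90.9% of genes changed 1.5, 2 and 4 times were recovered (10191 genes, 4 false among 150 calls). For day 50 daughters under HFD these shares were 49.3, 80.6 and 95.4% (10063 genes, 9 false among 158 calls), where DESeq2 made 35 false calls among 192. For HSD against HFD in day 10 daughters they were 11.9, 56.1 and 83.3% (10296 genes), and for day 50 sons under HFD 0, 7.46 and 60.6% (12589 genes). For the sex difference at day 50 under HFD they were 0, 19.4 and 54.5% (12726 genes) and for day dependence in daughters 5.97, 33.3 and 74.2% (10891 genes).

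Replicate libraries were checked for duplicates, and among 200 pairs within groups the lowest chi-square per degree of freedom was 5.74, so none was treated as a duplicate. The alternatives set in advance were DESeq2, median-of-ratios size factors, no low-count filter, other samples in the fit and leaving out each library in turn. After seeing the data 3 were added: leaving out the 5 libraries with transcripts of the other sex, leaving out also those placed at the same other day by age markers and by similarity over all genes, and a gonad score as a covariate. No library was removed from the main comparisons. Depth was compared by thinning counts to the smallest library, and shared controls by simulating unchanged groups against the CD libraries and by splitting those libraries.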

Results

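RNA was sequenced from whole flies of the white-eyed laboratory strain w1118 of Drosophila melanogaster. Mothers were fed a control diet (CD), a high fat diet (HFD) or a high sugar diet (HSD) for 7 days and then mated with males kept on CD. Their sons and daughters were raised on CD at 25 °C and collected on day 0, 10 or 50. The series asks how maternal obesity bears on the lifespan and immune function of the offspring, by diet and by sex. The 15 libraries of mothers fall into 3 groups of 5. The 87 progeny libraries, 44 male and 43 female, fall into 18 groups by maternal diet, sex and day. A group holds 5 libraries, with 4 exceptions: CD day 0 daughters (4), HSD day 50 daughters (4), HFD day 50 sons (3) and HSD day 50 sons (6). Libraries held from 6332907 to 19469296 counts, and 11387 to 13607 of the 14312 genes had a count. The 10 most abundant genes took 4.8 to 7.32% of the counts in mothers, 4.8 to 13% in male and 4.18 to 13.5% in female progeny. Values below are normalised CPM (mean ± SD) and log2 fold changes ± SE. Adjusted p are Benjamini-Hochberg values of edgeR's quasi-likelihood test, or of limma's camera test for a gene list, unless another tool is named. The labels do not say whether libraries of a group came from separate cultures, so p measures the spread between these libraries, which may be technical.

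Transcripts of the ovary and of the male accessory gland separated the sexes in most progeny libraries. The seminal fluid protein transcript Acp36DE reached 319 CPM or more in males with osk under 10 CPM and 0.21 CPM at most in the other females. The oocyte transcript osk, which was chosen after its values were seen, was 168 CPM or more in females with Acp36DE under 10 CPM and 0.925 CPM at most in the other males. In 5 libraries, 4 labelled male and 1 labelled female, osk or Acp36DE of the other sex exceeded 10 CPM. Day 0 sons m1, m3 and m4 of the CD group held osk at 18, 198 and 47.2 CPM and the yolk protein transcript Yp1 at 94.8, 349 and 536 CPM. The library labelled m8, an HFD day 0 son, held osk at 1330 CPM and Yp1 at 9710 CPM, with Acp36DE and the testis tubulin betaTub85D at 0, and was most similar to day 50 females. The library labelled f12, an HSD day 0 daughter, held Acp36DE at 451 CPM and betaTub85D at 228 CPM beside osk at 105 CPM, and was most similar to day 0 males. Among the other sons, with osk under 1 CPM, Yp1 was 22.2, 15.1, 16.1, 22 and 22.9 CPM in m27, m34, m35, m39 and m44. The age markers, chosen after seeing the data, were the lists of muscle, cuticle protein and larval fat body genes. They lay nearer to another day than the labelled day in 17 libraries. Among these, the library labelled m45, an HSD day 50 son, and those labelled f21 and f22, HFD day 10 daughters, lay nearest to day 0, as did f19, a CD day 10 daughter. All libraries stayed in their labelled groups.

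**Figure D1:**
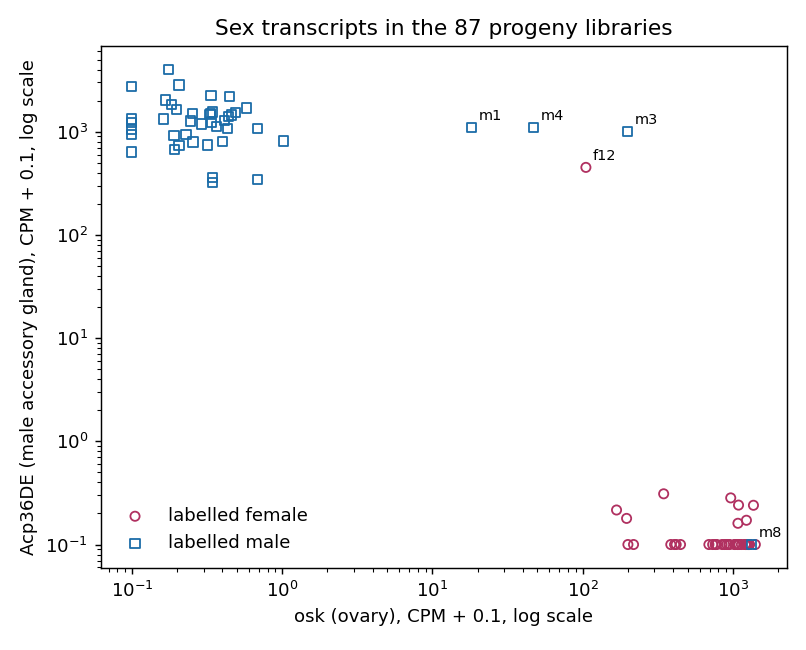
CPM of the oocyte transcript osk (x axis) against the accessory gland transcript Acp36DE (y axis), both plus 0.1 on log axes, in the 87 progeny libraries, with circles for libraries labelled female and squares for those labelled male. The 5 named libraries hold transcripts of the other sex: m8 lies among the females with osk at 1330 CPM, and f12 has Acp36DE at 451 CPM.

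In mothers, the comparison asks what 7 days of each diet did to the fly that received it. The highest-ranked gene in HFD against CD was Fad2, a desaturase of female pheromone synthesis, at 511 ± 167 against 216 ± 33.7 CPM (n = 5 each; log2 fold change 1.24 ± 0.21, adjusted p = 0.319). CG9458 (0.92 ± 0.18) and zye (3.02 ± 0.59) followed, both with adjusted p = 0.36. The mitochondrially encoded transcripts had a median log2 fold change of 0.28, with 8 of 13 higher when adjusted over the list alone (camera adjusted p = 1.15e-14; adjusted p = 0.343 with an estimated correlation). Transcripts of sugar digestion and transport had a median of −0.69 (adjusted p = 1.05e-06; adjusted p = 0.557 with an estimated correlation). In HSD against CD, the GABA transaminase Gabat was 132 ± 11.3 against 180 ± 21.7 CPM (−0.44 ± 0.08, adjusted p = 0.213). CG13947 was 4.1 ± 1.22 against 32.6 ± 30.2 CPM and ringer, a tubulin-binding protein, 29.2 ± 2.47 against 21.1 ± 1.2 CPM, at the same adjusted p. Neuronal transcripts had a median of 0.43 with 29 of 29 positive (adjusted p = 4.38e-13; adjusted p = 0.445 with an estimated correlation). Gut serine proteases had a median of −0.60 with 6 of 27 lower when adjusted over the list alone (adjusted p = 8.46e-12; adjusted p = 0.263 with an estimated correlation). Between the diets, the gut protease Jon66Ci was 7.58 ± 4.31 CPM in HSD and 29.3 ± 12.9 CPM in HFD. Sox14 and CG34253 had log2 fold changes of 0.53 ± 0.11 and 1.10 ± 0.26 (adjusted p = 0.609 for these genes and Jon66Ci). By edgeR, 0 of 10243 genes passed in each of the 3 comparisons, with 314, 949 and 831 genes at an unadjusted p under 0.05 for HFD against CD, HSD against CD and HSD against HFD. DESeq2 called 15, 38 and 1.

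In day 0 daughters, the genes ranked highest in HFD against CD were Gabat, at 143 ± 28 (n = 5) against 89.5 ± 12.4 CPM (n = 4). Sbat (0.87 ± 0.22) and the translation factor DENR (0.43 ± 0.12) followed, and all had adjusted p = 0.717. Nuclear transcripts of oxidative phosphorylation had a median log2 fold change of −0.41 (adjusted p = 1.90e-19; adjusted p = 0.768 with an estimated correlation). These transcripts fell from day 0 to day 10 in CD daughters. Over all genes the HFD libraries f8 and f10 and the HSD libraries f13 and f15 are most similar to day 10 daughters. Of these, f13 and f15 also lie nearest to day 10 by age markers. In HSD against CD, CG46491 (0.74 ± 0.18), the prophenoloxidase PPO2 of crystal cells (1.93 ± 0.52) and the stress peptide TotA (1.81 ± 0.49) had an adjusted p = 1. Hemocyte and melanisation genes had a median of 0.44, with 3 of 19 past the threshold when adjusted over the list alone (adjusted p = 6.58e-13; adjusted p = 0.123 with an estimated correlation). In HSD against HFD, CG46491, puml and CG6484 had log2 fold changes of 0.96 ± 0.17, 0.78 ± 0.16 and 1.60 ± 0.33 (adjusted p = 0.333). Of the cytochrome P450s 69 of 80 were positive (adjusted p = 2.14e-10; adjusted p = 0.385 with an estimated correlation). With f12 among the HSD libraries, 5 of 8 testis and 4 of 4 accessory gland transcripts were higher than in HFD when adjusted over each list alone (adjusted p = 0.0374 and 0.00596; adjusted p = 0.703 and 0.42 with an estimated correlation). By edgeR, 0 of 10630 genes passed in HFD against CD, HSD against CD and HSD against HFD, with 280, 299 and 1313 at an unadjusted p under 0.05. DESeq2 called 0, 0 and 147.

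In day 0 sons, the highest-ranked genes in HFD against CD were the glutathione S-transferase GstE7, at 14.3 ± 2.54 against 8.53 ± 1.55 CPM (n = 5 each), and Acbp6 (1.62 ± 0.41). The eggshell protein Cp15 was 228 ± 504 against 1.78 ± 0.562 CPM, and all had adjusted p = 0.991. The spread of Cp15 goes with m8, whose female transcripts are given above. Gut serine proteases had a median log2 fold change of 0.83 (adjusted p = 1.21e-08; adjusted p = 0.793 with an estimated correlation). In HSD against CD, CG7695 (1.10 ± 0.23), CG43739 (−4.26 ± 1.04) and CG14257 (−3.33 ± 0.82) had adjusted p = 0.974, and gut serine proteases a median of 0.86 (adjusted p = 5.86e-14; adjusted p = 0.496 with an estimated correlation). In HSD against HFD, CG42366 was 3.34 ± 0.863 against 1.18 ± 0.485 CPM, and CG43739 and the guanylyl cyclase Gyc32E had log2 fold changes of −4.42 ± 1.04 and 1.55 ± 0.37 (adjusted p = 0.535). Cell cycle transcripts, which m8 carries as the female libraries do, had a median of −2.65, with 22 of 26 lower when adjusted over the list alone (adjusted p = 3.22e-07; adjusted p = 0.92 with an estimated correlation). By edgeR, 0 of 12591 genes passed in HFD against CD, HSD against CD and HSD against HFD, with 221, 383 and 1085 at an unadjusted p under 0.05. DESeq2 called 1, 5 and 2. Without m8, edgeR called 3 genes in HFD against CD, and without m13 it called 1 in each of the other comparisons.

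In day 10 daughters of HFD mothers, 4 genes rose and 1 fell against CD, of 10354 tested (n = 5 each). The tyrosine aminotransferase Tat, at the entry of tyrosine breakdown, rose to 53.6 ± 8.78 from 12.6 ± 3.27 CPM (2.10 ± 0.32, adjusted p = 0.0252). The transcription factor trh (trachealess) rose to 11.3 ± 1.3 from 5.45 ± 0.89 CPM and the metalloprotease Invadolysin to 120 ± 12.1 from 67.1 ± 10.6 CPM (adjusted p = 0.0252 for both). The purine synthesis enzyme Paics rose to 271 ± 48.7 from 158 ± 16.5 CPM (adjusted p = 0.0268). CG8093 fell to 2.61 ± 1.12 from 33.1 ± 12 CPM (−3.66 ± 0.53, adjusted p = 0.0252). The later enzymes of tyrosine breakdown did not pass: Hpd was 109 ± 57.2 against 14.9 ± 9.41 CPM (adjusted p = 0.0649) and hgo 16.1 ± 2.98 against 5.29 ± 1.71 CPM (adjusted p = 0.071). Of 72 nuclear genes of oxidative phosphorylation 71 were higher when adjusted over the list alone, with a median of 0.74 (adjusted p = 5.31e-32; adjusted p = 0.584 with an estimated correlation), although 0 passed over all genes tested. All 72 fell from day 0 to day 10 in CD daughters, and the HFD libraries f21 and f22 and the CD library f19 lie nearest to day 0 by age markers. All 5 calls were lost without f16, f17, f18, f20, f22, f23, f24 or f25, with adjusted p of up to 0.115 for Paics and 0.11 for Tat, trh and Invadolysin. Without f19 or f21, 623 or 413 genes were called. In alternatives chosen after seeing the data, edgeR called 582 without f21, f22, f26 and f27, and 0 with the gonad score as a covariate. DESeq2 called 928, 755 higher and 173 lower. At an adjusted p under 0.1, edgeR called 270 genes higher and 53 lower.

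In day 10 daughters of HSD mothers against CD (n = 5 each), the 3 highest-ranked genes encode Bomanins, short secreted peptides of the Toll immune response. BomS3 was 50.6 ± 25.5 against 200 ± 45.2 CPM (−1.98 ± 0.32), BomS6 9.54 ± 2.51 against 26.5 ± 4.81 CPM (−1.47 ± 0.23) and BomT2 18.1 ± 5.8 against 50.4 ± 6.74 CPM (−1.48 ± 0.23), each with adjusted p = 0.0646. All 14 of 14 Bomanins and Daisho peptides were lower when adjusted over the list alone, with a median of −1.78 (adjusted p = 8.33e-24; adjusted p = 0.116 with an estimated correlation; fry adjusted p = 0.00258). Oxidative phosphorylation had a median of −0.65, with 66 of 72 lower when adjusted over the list alone (adjusted p = 1.35e-25; adjusted p = 0.571 with an estimated correlation). Muscle transcripts had a median of −1.29, with 11 of 22 lower by the same count (adjusted p = 1.03e-10; adjusted p = 0.571 with an estimated correlation). Both lists fell with age in CD daughters, and the HSD libraries f26, f27 and f28 lie nearest to day 50 by age markers. The age markers include the muscle list, so this placement is not independent of the muscle values. EdgeR called 0 genes of 10354, with 2397 at an unadjusted p under 0.05, and DESeq2 called 241, of which 2 were shared with HFD against CD and 42 were opposite to it. Without f29, an HSD library, edgeR called 1350.

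Day 10 daughters of HSD and HFD mothers differed in 6867 of 10354 genes, 3303 higher and 3564 lower in HSD (n = 5 each). All 72 nuclear genes of oxidative phosphorylation were lower in HSD, with a median log2 fold change of −1.39 (adjusted p = 3.30e-34; adjusted p = 0.585 with an estimated correlation). Among them COX5B fell by 1.57 ± 0.20 and ATPsynO by 1.66 ± 0.22, and 11 of 13 mitochondrially encoded transcripts were lower, mt:ND2 at 11.5 ± 2.18 against 37.6 ± 7.64 CPM (adjusted p = 0.00106). In glycolysis 12 of 13 genes fell, with Gapdh1 at 934 ± 173 against 2850 ± 648 CPM and Pfk at 222 ± 37.3 against 520 ± 56.8 CPM (list adjusted p = 2.60e-05; adjusted p = 0.585 with an estimated correlation). All 22 muscle genes fell, the flight muscle actin Act88F to 311 ± 300 from 3860 ± 2310 CPM (adjusted p = 0.00269) and Strn-Mlck by 2.78 ± 0.48 (list adjusted p = 6.11e-08; adjusted p = 0.585 with an estimated correlation). Of the Bomanins and Daisho peptides 11 of 14 fell, BomS3 to 50.6 ± 25.5 from 193 ± 72.7 CPM (list adjusted p = 8.08e-05; adjusted p = 0.585 with an estimated correlation), and 7 were called without f22, f26, f27 or f30. The protease psh and the serpin nec, both upstream of Toll, fell by 1.79 ± 0.29 and 1.63 ± 0.29. Hemocyte and melanisation genes were lower in 15 of 19 and cuticle proteins in 26 of 38 (adjusted p = 6.32e-04 and 2.55e-05; adjusted p = 0.585 for both with an estimated correlation).

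Among the rises in the same comparison were genes of proliferation, the germline and chromatin. All 26 genes of the cell cycle and DNA replication rose, with Orc2 at 64.3 ± 15.2 against 19.7 ± 9.48 CPM (1.70 ± 0.39, adjusted p = 0.00363). Their median was 1.33 (list adjusted p = 6.96e-09; adjusted p = 0.585 with an estimated correlation). Of the ovarian germline genes 26 of 32 rose, spn-E, a helicase of the piRNA pathway, to 160 ± 40.3 from 54.2 ± 25 CPM (list adjusted p = 7.69e-06; adjusted p = 0.585 with an estimated correlation). Of the Polycomb, heterochromatin and histone methylation genes 27 of 30 rose, the methyltransferase ash1 to 175 ± 26.4 from 80.5 ± 20.4 CPM (list adjusted p = 1.16e-07; adjusted p = 0.585 with an estimated correlation). Jarid2 had a log2 fold change of 0.93 ± 0.19 (adjusted p = 0.00263). The HFD libraries f21 and f22 lie nearest to day 0 by age markers, and f22 has a mean log2 CPM of 3.59 over the ovarian germline list, against 5.83 to 6.17 in the other HFD libraries. The HSD libraries f26, f27 and f28 lie nearest to day 50, and of these f28 is most similar to day 10 daughters over all genes. Without f21, f22, f26 and f27, an alternative chosen after seeing the data, 3277 genes were called, 2928 of them also called with all libraries. With the gonad score as a covariate, likewise chosen after seeing the data, 902 calls were left, 876 of them shared. Act88F, Jarid2 and spn-E then had log2 fold changes of −2.61, 0.47 and 0.55 (adjusted p = 0.0518, 0.0524 and 0.069). The ovarian germline mean was 6.41 or more in the HSD and 6.17 at most in the HFD libraries. The groups thus lie apart on this list, and the fit with the gonad score cannot tell ovary share from diet. Of the ovarian germline genes 16 were called without f27.

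**Figure D2:**
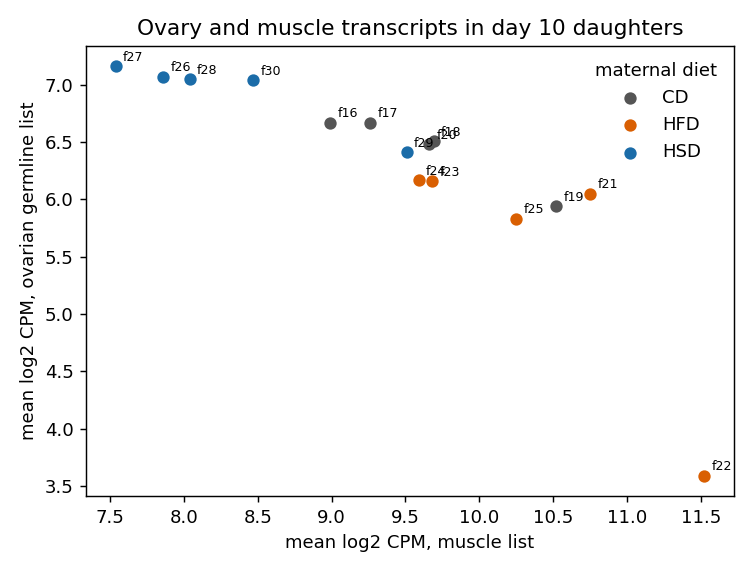
Mean log2 CPM over the muscle list (x axis) and the ovarian germline list (y axis) in the day 10 daughter libraries, with a named point per library coloured by maternal diet. Library f22 has an ovarian germline value of 3.59, f19 one of 5.94, and muscle transcripts were lower in the HSD than in the HFD libraries, with a median log2 fold change of −2.16.

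In day 10 sons, HFD against CD ranked Cyp6a17 first, at 48.2 ± 6.78 against 81.7 ± 6.74 CPM (n = 5 each, adjusted p = 0.253). It was followed by CG9416 (1.19 ± 0.23, adjusted p = 0.93) and the fat body hormone CCHa2 (0.65 ± 0.14, adjusted p = 1). The mitochondrially encoded transcripts were lower as a list, with a median of −0.29 and 3 of 13 lower when adjusted over the list alone (adjusted p = 9.32e-17; adjusted p = 0.0456 with an estimated correlation). In HSD against CD, the tyrosine breakdown enzymes hgo, at 55.8 ± 10.4 against 97.5 ± 9.54 CPM (adjusted p = 0.134), and Tat, at 117 ± 15.1 against 176 ± 15.7 CPM (adjusted p = 0.208), ranked high. The odorant binding protein Obp99b was 154 ± 44.1 against 564 ± 209 CPM (adjusted p = 0.208). In HSD against HFD, CG9416 (−1.55 ± 0.23), CG10621 (−0.75 ± 0.12) and the argininosuccinate lyase Argl (−0.60 ± 0.10) had adjusted p = 0.0935. Adult fat body transcripts were lower as a list, with a median of −0.25 and 7 of 16 lower when adjusted over the list alone (adjusted p = 3.97e-12; adjusted p = 0.0165 with an estimated correlation; fry adjusted p = 0.00984). By edgeR, 0 of 12518 genes passed in HFD against CD, HSD against CD and HSD against HFD, with 319, 406 and 542 at an unadjusted p under 0.05. DESeq2 called 3, 20 and 46. Without m27, which has testis transcripts at a mean log2 CPM of 2.83 against 6.78 to 7.28 in the other HSD sons, edgeR called 7 genes in HSD against CD and 48 in HSD against HFD. The latter count was 3 without m28 and 1 without m29.

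In day 50 daughters of HFD mothers, 563 genes fell and 69 rose against CD, of 10132 tested (n = 5 each). Genes of the gut lumen were among the falls. Of the genes for sugar digestion and transport 10 of 17 fell, 11 when adjusted over the list alone, with a median of −2.11 (adjusted p = 2.16e-15; adjusted p = 0.0532 with an estimated correlation; fry adjusted p = 6.20e-04). The maltases Mal-A1 and Mal-A6 fell to 11.6 ± 6.74 from 308 ± 84.8 CPM and to 6.62 ± 4.41 from 157 ± 32.8 CPM (adjusted p = 9.23e-04 and 4.49e-04). The glucosidase tobi, a target of brain insulin, fell by 3.31 ± 0.37 (adjusted p = 2.33e-04). Of the gut serine proteases 9 of 27 fell, 14 when adjusted over the list alone (adjusted p = 2.23e-15; adjusted p = 0.423 with an estimated correlation). Ser8 was 0.148 ± 0.248 against 15.4 ± 4.88 CPM and Jon66Cii 0.538 ± 0.619 against 30.2 ± 4.62 CPM. The sterol uptake genes Npc1b and Npc2e fell to 1.6 ± 1.54 from 84.2 ± 28.5 CPM and to 7.5 ± 4.51 from 143 ± 25.8 CPM (adjusted p = 0.00165 and 1.37e-04). The storage protein Lsp2 had the smallest adjusted p, 0.249 ± 0.108 against 19.6 ± 9.56 CPM (adjusted p = 6.80e-05), and the glucocerebrosidase Gba1a fell by 5.28 ± 0.54 on the log2 scale (adjusted p = 2.03e-04). The 10 calls on sugar digestion and transport became 6 without f32 or f38, and the 9 on gut serine proteases 17, 4 and 5 without f36, f38 and f39.

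Genes of immunity, the fat body and detoxification also fell in these daughters. Of the immune recognition and Toll/Imd genes 8 of 39 fell, 10 when adjusted over the list alone (adjusted p = 2.08e-04; adjusted p = 0.372 with an estimated correlation). Among them were PGRP-LB (−1.21 ± 0.21, adjusted p = 0.00381) and pirk (−1.80 ± 0.34, adjusted p = 0.006), both inhibitors of Imd signalling. The Relish partner Charon was 35.8 ± 6.16 against 71.7 ± 7.56 CPM (adjusted p = 2.27e-04). Of the antimicrobial peptides 2 of 20 fell, also when adjusted over the list alone: Drsl2 by 3.63 ± 0.76 (adjusted p = 0.011) and AttD by 2.51 ± 0.70 (adjusted p = 0.0489), with a list adjusted p = 0.183. Of the adult fat body genes 6 of 16 fell, 7 when adjusted over the list alone (adjusted p = 1.08e-07; adjusted p = 0.14 with an estimated correlation). Of the cytochrome P450s 15 of 78 fell, 20 when adjusted over the list alone (adjusted p = 1.15e-05; adjusted p = 0.826 with an estimated correlation), with log2 fold changes of −4.26 ± 0.40 for Cyp304a1 and −3.59 ± 0.35 for Cyp309a1. The stress peptide TotA fell to 10.6 ± 4.12 from 60.4 ± 32.8 CPM (adjusted p = 0.00437). Among the rises were the glutathione S-transferase GstE4, to 3.8 ± 1.5 from 0.682 ± 0.19 CPM (adjusted p = 0.0027), and the hemocyte gene Hml, to 25.9 ± 2.21 from 12.5 ± 3.76 CPM (adjusted p = 0.0163). The call on AttD was lost without f31, f32, f33, f34, f36, f37, f38 or f39 (adjusted p up to 0.141) and that on Hml without f32 (adjusted p = 0.0521). In a fit over all 9 groups of daughters both were lost (adjusted p = 0.318 and 0.304), and AttD also without a count filter (adjusted p = 0.0534). With the gonad score as a covariate, chosen after seeing the data, 695 genes fell and 529 rose. The 8 immune recognition calls became 5 without f31, f32, f33, f38 or f39. The count of calls was 407, 420, 413 and 410 without f32, f37, f38 and f39.

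In day 50 daughters of HSD mothers (n = 4) against CD (n = 5), 665 genes fell and 296 rose of 10132 tested. Of the antimicrobial peptides 7 of 20 fell, 12 when adjusted over the list alone, with a median log2 fold change of −3.24 (adjusted p = 1.36e-06; adjusted p = 0.419 with an estimated correlation; fry adjusted p = 0.0342). The drosomycin-like peptide Drsl2 fell to 0.997 ± 1.18 from 51.3 ± 12.6 CPM (adjusted p = 0.00434), the attacin AttD to 1.65 ± 0.457 from 27.9 ± 20.6 CPM (adjusted p = 0.0112). The diptericin DptA fell to 5.27 ± 4.14 from 233 ± 163 CPM (adjusted p = 0.0235). Of the immune recognition and Toll/Imd genes 9 of 39 fell, likewise 9 when adjusted over the list alone (adjusted p = 2.19e-04; adjusted p = 0.305 with an estimated correlation). The peptidoglycan receptors PGRP-SB1 and PGRP-SD fell to 6.58 ± 1.55 from 85.9 ± 19.1 CPM and to 7.74 ± 1.7 from 30.9 ± 10.1 CPM (adjusted p = 0.00276 and 0.00337). Charon fell to 33.7 ± 1.99 from 71.7 ± 7.56 CPM (adjusted p = 2.22e-04). The cytokine upd3 fell to 0.39 ± 0.112 from 2.57 ± 0.62 CPM (adjusted p = 0.00626) and Socs36E, an inhibitor in the pathway it activates, by 1.37 ± 0.28 (adjusted p = 0.0108). IBIN, a small immune-induced transcript, had 2 counts in the 4 HSD libraries and 653 in the 5 CD libraries, a CD to HSD ratio of 270 (95% counting interval 74.4 to 2230, adjusted p = 0.0131). This interval, like that of Lsp2 below, is of pooled counts and leaves out the spread between libraries. The log2 fold change of IBIN was −7.81 ± 1.68. Of the sugar digestion and transport genes 8 of 17 fell, 12 when adjusted over the list alone (adjusted p = 6.93e-10; adjusted p = 0.0638 with an estimated correlation). Mal-A6 fell to 16 ± 15.2 from 157 ± 32.8 CPM and tobi by 3.03 ± 0.40. Of the gut serine proteases 4 of 27 fell and 1 rose, with 7 lower and 1 higher when adjusted over the list alone (adjusted p = 5.36e-06; adjusted p = 0.48 with an estimated correlation). The 1 that rose was zetaTry, to 6.94 ± 5.61 from 1.62 ± 0.76 CPM (adjusted p = 0.0383), a call lost without f31, f32, f33, f34, f35, f43 or f44 (adjusted p up to 0.141). The 5 calls became 1, 2, 3, 1 and 3 without f31, f32, f33, f34 and f35 and 2, 3 and 1 without f41, f42 and f43.

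The lysozymes divided in the HSD daughters: LysX fell to 0.09 ± 0.18 from 39.1 ± 26.2 CPM (adjusted p = 0.00333), while LysD rose to 208 ± 157 from 19.3 ± 13.5 CPM (3.42 ± 0.83, adjusted p = 0.022). Reads of LysD may be shared with its near-identical copies such as LysB, so the split between them is uncertain. Lsp2 had 1 count in the HSD and 1104 in the CD libraries, a CD to HSD ratio of 912 (95% counting interval 163 to 36100, adjusted p = 4.00e-05), and Npc2e and Cyp304a1 fell by 5.89 ± 0.50 and 6.46 ± 0.52. The methionine-cycle enzyme Gnmt and the urate oxidase Uro fell to 1.44 ± 0.597 from 14.7 ± 5.2 CPM and to 38 ± 12.4 from 127 ± 34 CPM (adjusted p = 0.00264 and 0.00366). Photoreceptor genes rose in 13 of 28, 21 when adjusted over the list alone (median 0.94; adjusted p = 8.71e-14; adjusted p = 0.305 with an estimated correlation). Neuronal genes rose in 12 of 29, 22 when adjusted over the list alone (median 0.72), with the same adjusted p. The opsin Rh5 rose by 1.95 ± 0.46 and the acetylcholine transporter VAChT to 11.2 ± 2.92 from 4.87 ± 0.619 CPM (adjusted p = 0.0192 and 0.00626). Of the hemocyte and melanisation genes 5 of 18 rose (adjusted p = 0.006; adjusted p = 0.419 with an estimated correlation), with 8 higher and 2 lower when adjusted over the list alone. Hml rose to 36.8 ± 13.6 from 12.5 ± 3.76 CPM and the scavenger receptor Sr-CI by 1.48 ± 0.31.

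Several calls of the HSD comparison at day 50 rested on few libraries. The 7 antimicrobial peptide calls became 3, 3, 4, 3 and 4 without f31, f32, f33, f34 and f35 and 3, 2 and 2 without f41, f42 and f43. Of these, Mtk and Dro were not called without any 1 of the 9 libraries (adjusted p up to 0.125 and 0.119). DptB was not called without f31, f32, f34, f41, f42 or f43 (adjusted p up to 0.0935), DptA without f41, f42 or f43 (0.0769), IBIN without f43 (0.0509), LysD without f31, f34, f43 or f44 (0.0626) and Rh5 without f34, f41 or f43 (0.0597). The 13 photoreceptor calls became 4, 2, 8, 1, 0 and 3 and the 12 neuronal calls 5, 3, 7, 2, 1 and 5 without f31, f34, f35, f41, f43 and f44. The 8 calls on sugar digestion and transport became 5 and 4 without f41 and f43, and the 5 on hemocyte and melanisation genes 2, 2, 3, 2 and 2 without f31, f32, f34, f41 and f44. The total was 450, 467, 411 and 399 calls without f31, f34, f41 and f43. In a fit over all 9 groups of daughters, HFD against CD had 359 calls and HSD against CD 268. DptA, DptB, AttD, Mtk, Dro, PGRP-SD, LysD, Mal-A6, tobi, zetaTry, Rh5, VAChT and Hml were among the calls lost in HSD (adjusted p up to 0.255). Mtk and Dro were also lost without a count filter (adjusted p = 0.0536 and 0.0531), and Mtk with median-of-ratios size factors. With the gonad score as a covariate, chosen after seeing the data, 1237 genes fell and 905 rose in HSD.

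**Figure D3:**
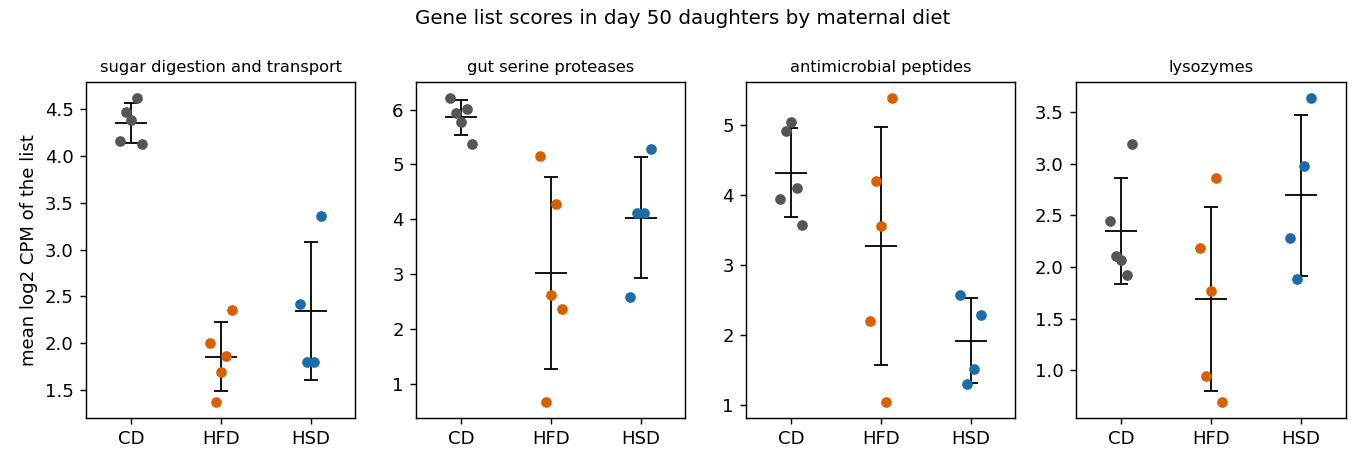
Mean log2 CPM over 4 gene lists (sugar digestion and transport, gut serine proteases, antimicrobial peptides, lysozymes) in each day 50 daughter library by maternal diet, with points for libraries, bars for the mean and error bars for the SD. Against CD, the sugar digestion list has a median log2 fold change of −2.11 in HFD and −1.88 in HSD, and the antimicrobial peptides −0.12 in HFD and −3.24 in HSD.

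The falls against CD overlapped between the diets at day 50. In both comparisons 394 genes were lower and 32 higher, and 0 were called in opposite directions, where independent lists of these sizes would share 37 and 2.02. Groups drawn to be unchanged against the same CD libraries shared 0 calls on average and 0 at most in 20 draws. Fold changes correlated across genes with r = 0.801, against 0.467 in those draws, and the covariance was 0.38 against 0.0372. Genes are not independent replicates. When the CD libraries were split so that each diet met other CD libraries, 76 to 211 calls were shared over 20 splits, 71 or more of them lower. Compared directly, HSD (n = 4) against HFD (n = 5) gave 0 calls of 10132 by edgeR, with 1566 at an unadjusted p under 0.05, 333 by DESeq2 and 326 by edgeR without f40. The highest-ranked genes were Sas10 (−0.28 ± 0.04), meigo (−0.24 ± 0.04) and Cftr (−0.39 ± 0.07), each with adjusted p = 0.123. When adjusted over each list alone, 23 of 28 photoreceptor genes were higher in HSD (adjusted p = 6.58e-23; adjusted p = 0.491 with an estimated correlation). By the same count 11 of 20 antimicrobial peptides were lower, with a median of −2.53 (adjusted p = 1.86e-06; adjusted p = 0.506 with an estimated correlation). Several peptides of this list varied widely between the HFD libraries, AttA at 174 ± 309 and Dro at 291 ± 465 CPM. Drs, at 473 ± 224 CPM, varied less.

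In day 50 sons of HFD mothers (n = 3) against CD (n = 5), the testis and sperm genes stood out as a list. All 40 had a positive log2 fold change, with a median of 2.69, and 38 were higher when adjusted over the list alone (adjusted p = 1.33e-15; adjusted p = 0.977 with an estimated correlation). Their mean log2 CPM per library was 6.30 ± 0.13 in HFD and 3.47 ± 1.51 in CD sons (exact permutation p = 0.0357, the smallest possible with 3 against 5 libraries). Accessory gland genes were higher in 15 of 32 when adjusted over the list alone (adjusted p = 4.69e-08; adjusted p = 0.977 with an estimated correlation). The seminal peptide transcript Acp54A1 was 49.6 ± 11 against 7.5 ± 3.69 CPM (2.73 ± 0.41, adjusted p = 0.0648). The elongase eloF, which acts in the synthesis of female pheromones, was 0.27 ± 0.022 against 4.64 ± 1.32 CPM (−4.04 ± 0.54, adjusted p = 0.0565), and CG1077 4.29 ± 1.7 against 0.904 ± 0.213 CPM (adjusted p = 0.0648). In HSD sons (n = 6) the testis score was 5.11 ± 1.33 (exact permutation p = 0.0996 against CD), with m40 and m45 at 6.14 and 6.91 and the others at 5.57 or less. There GstE4, CG10051 and CG15930 had log2 fold changes of 1.49 ± 0.28, −2.17 ± 0.41 and −2.43 ± 0.46 (adjusted p = 0.302). Between HSD and HFD, eloF (2.25 ± 1.15 against 0.27 ± 0.022 CPM, adjusted p = 0.766) and CG43093 (−0.83 ± 0.17, adjusted p = 0.848) ranked first. By edgeR, 0 of 12659 genes passed in HFD against CD, HSD against CD and HSD against HFD, with 3627, 2057 and 626 at an unadjusted p under 0.05. DESeq2 called 2429, 29 and 14. At an adjusted p under 0.1, edgeR called 1498 genes higher and 331 lower in HFD against CD, and 0 in HSD against CD. Without m45, an HSD library with age markers nearest to day 0, edgeR called 1 gene in HSD against CD. The age markers of m35, m39, m40 and m42 lie nearest to day 10. Over all genes m40 and the 3 HFD libraries, m36, m38 and m39, are most similar to day 10 sons. Without m39, m40 and m45, an alternative chosen after seeing the data that leaves 2 HFD libraries, HFD against CD had 507 calls, 382 higher and 125 lower. Without m39 alone it had 0, and with other samples in the fit and no library left out 2365.

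**Figure D4:**
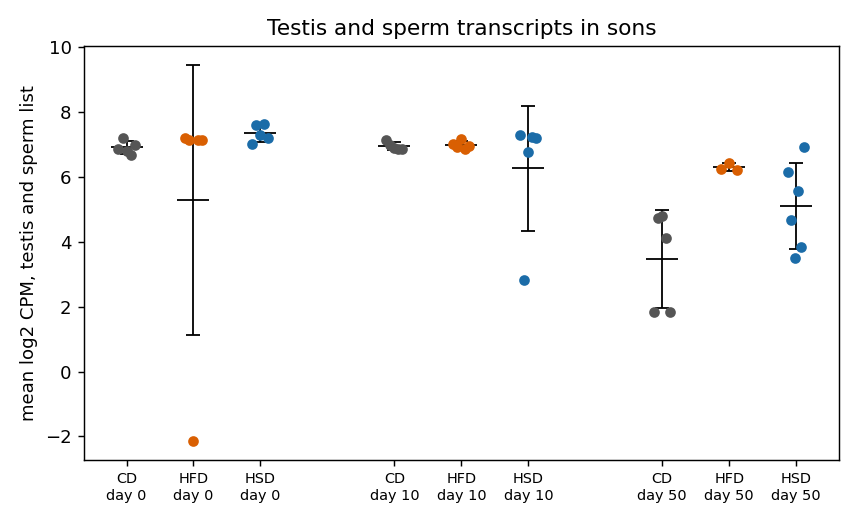
Mean log2 CPM over the testis and sperm list in each library of sons, by maternal diet and day, with points for libraries, bars for the mean and error bars for the SD. At day 50 the value was 6.30 ± 0.13 in HFD sons (n = 3), 5.11 ± 1.33 in HSD sons (n = 6) and 3.47 ± 1.51 in CD sons (n = 5), and m8 at day 0 lies at −2.14.

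Whether a maternal diet acted differently on daughters and sons was tested as the difference of the diet effects, female minus male. At day 10, the effect of HFD on Tat differed by 2.07 ± 0.33 (adjusted p = 0.0142), with a log2 fold change of 2.10 in daughters and −0.06 in sons, and was the 1 call of 12839. The differences for hgo (1.77 ± 0.35) and Hpd (2.86 ± 0.58) had adjusted p = 0.0886. The call on Tat was lost without f17 (adjusted p = 0.0501), and the count was 344 without f19, 80 without f21, 3 without f16 and 2 without f18, m20, m22 or m24. At day 50, the effect of HFD differed for 26 of 12872 genes, 8 higher and 18 lower in daughters. The effect on eloF differed by 5.09 ± 0.68 (adjusted p = 0.00107), from 1.09 ± 0.34 in daughters and −4.04 ± 0.54 in sons, and that on Lsp2 by −7.10 ± 1.13 (adjusted p = 0.0097). The effect of HSD differed for 14 genes, 3 higher and 11 lower, among them Cyp304a1 (−5.35 ± 0.82, adjusted p = 0.00542) and Lsp2 (adjusted p = 0.00298), whose HSD level in daughters is near the floor. The call on Lsp2 under HFD was lost without m39 (adjusted p = 0.0682) and that on Cyp304a1 without f43 (adjusted p = 0.0728). Under HFD the calls on eloF and Lsp2 were lost in a fit over all 18 progeny groups (adjusted p = 0.105 for both). With median-of-ratios size factors the split was 12 higher and 17 lower for HFD and 6 and 7 for HSD.

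The counts at day 50 moved with most libraries. For HFD the 26 calls became 16, 9, 8, 17 and 1 without m33, m34, m36, m38 and m39. They became 11, 9, 10, 7 and 53 without f31, f32, f33, f34 and f35, and 176, 7, 9 and 17 without f36, f37, f39 and f40. For HSD the 14 calls became 5, 6, 6, 7 and 3 without m31, m32, m33, m34 and m35, and 7, 4 and 91 without m41, m43 and m45. They became 5, 2, 4, 7 and 7 without f31, f32, f33, f34 and f35, and 4, 6, 1 and 3 without f41, f42, f43 and f44. In the comparisons with no call, the highest-ranked genes were CG11425 at day 0 for HFD (1.29 ± 0.41, adjusted p = 1), and Atg2 at day 0 for HSD (0.64 ± 0.15, adjusted p = 0.383). At day 10 for HSD it was BomS6 (−1.63 ± 0.33, adjusted p = 0.34). EdgeR called 0 genes there, with 117 and 1569 of 12919 and 1773 of 12839 at an unadjusted p under 0.05, and DESeq2 called 206, 575 and 10. The last edgeR count was 307 without f29.

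Ageing of CD daughters, the background against which the maternal diets are read, changed 7504 of 10526 genes from day 0 (n = 4) to day 10 (n = 5), 3854 upward and 3650 downward. All 27 gut serine proteases rose, with a median of 2.94 (adjusted p = 2.66e-09; adjusted p = 0.597 with an estimated correlation), etaTry to 20 ± 1.67 from 6.43 ± 1.92 CPM. All 72 oxidative phosphorylation genes and all 22 muscle genes fell, with medians of −1.37 and −1.97 (adjusted p = 8.58e-31 and 3.60e-10; adjusted p = 0.597 for both with an estimated correlation). The muscle actin Act79B fell to 1530 ± 801 from 7250 ± 796 CPM. Ovarian germline genes rose in 29 of 32, osk by 1.10 ± 0.11 to 950 ± 135 CPM (adjusted p = 8.69e-06; list adjusted p = 5.46e-08; adjusted p = 0.597 with an estimated correlation). From day 10 to day 50 (n = 5 each), 1695 genes rose and 3168 fell. Antimicrobial peptides rose in 10 of 19 and fell in 1 (adjusted p = 0.00388; adjusted p = 0.672 with an estimated correlation), with 7 called without f17, f18 or f32. Drsl2 rose to 43.5 ± 10.4 from 1.03 ± 0.461 CPM, PGRP-SB1 by 3.88 ± 0.24 and LysX by 5.88 ± 0.78. All 22 muscle genes fell further, with a median of −3.58 (adjusted p = 4.44e-34; adjusted p = 0.437 with an estimated correlation).

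In CD sons, 3521 of 12609 genes changed from day 0 to day 10 (n = 5 each), 2018 upward and 1503 downward. Muscle genes fell in 19 of 22 (median −2.45, adjusted p = 4.74e-43) and adult fat body genes rose in 13 of 16 (median 2.03, adjusted p = 4.12e-13), each with adjusted p = 0.0116 with an estimated correlation. Cytochrome P450s rose in 50 and fell in 7 of 81 (adjusted p = 0.0273 with an estimated correlation). Cuticle proteins fell in 25 and rose in 8 of 55 (adjusted p = 0.00129 with an estimated correlation), with the adult cuticle protein Acp65Aa at 0.145 ± 0.159 against 286 ± 114 CPM. PPO1 rose to 34.8 ± 11.3 from 0.222 ± 0.223 CPM. From day 10 to day 50, 8310 genes changed, 4304 upward and 4006 downward (n = 5 each). All 40 testis and sperm genes fell, with a median of −3.43 (adjusted p = 5.22e-11; adjusted p = 0.883 with an estimated correlation), topi to 7.13 ± 1.66 from 20.4 ± 1.1 CPM. Of the genes tested, 84 of 93 cytosolic ribosomal protein genes rose while 3 fell (adjusted p = 1.57e-19; adjusted p = 0.883 with an estimated correlation). Immune recognition and Toll/Imd genes rose in 30 of 39 and fell in 2 (adjusted p = 9.74e-07; adjusted p = 0.398 with an estimated correlation). Charon rose to 102 ± 10.8 from 13.1 ± 0.555 CPM (adjusted p = 1.47e-09), Sting to 78.2 ± 7.33 from 13.8 ± 1.87 CPM and the transcription factor Rel by 1.73 ± 0.16. Bomanins and Daisho peptides rose in 12 of 15, BomS3 to 645 ± 364 from 142 ± 70.5 CPM (adjusted p = 1.40e-04; list adjusted p = 0.00731; adjusted p = 0.883 with an estimated correlation).

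Whether maternal diet effects depended on the day was tested over all days at once. In daughters 5275 of 10971 genes passed, with CG8353 (adjusted p = 6.62e-07), CG7829 (8.36e-06), Srg1 (1.46e-05), Cyp309a1 (1.46e-05) and CG13323 (1.48e-05) at the smallest values, and the count was 3339 without f22. In sons edgeR called 0 of 13058, with 2139 at an unadjusted p under 0.05 and a lowest adjusted p = 0.0914 for phu, and DESeq2 called 81. Leaving out m8 gave 22 calls, m9 2, and m6, m7, m10, m19, m24, m27, m29 or m41 1 each. Calls of mothers and progeny could not overlap, since edgeR called 0 genes in mothers. By DESeq2, mothers shared 6 calls with day 50 daughters under HFD and 9 under HSD, with 0 and 2 in opposite directions. Daughters and sons shared 0 edgeR calls at each day for each diet, since at most 1 of the sexes had calls, and by DESeq2 197 at day 50 under HFD, with 10 called in opposite directions.

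Coordinates are of build BDGP6.54, and each gene is protein-coding, with counts over its transcripts. Tat (FBgn0030558) lies on chromosome X at 14261223 to 14265379 on the + strand. Lsp2 (FBgn0002565) lies on 3L at 12129393 to 12131869 (+). Mal-A1 (FBgn0002570) and Mal-A6 (FBgn0050360) lie in the maltase cluster of 2R at 8449664 to 8451904 (−) and 8465158 to 8467595 (+), and DptA (FBgn0004240) and DptB (FBgn0034407) neighbour each other on 2R at 18865765 to 18866260 (+) and 18867391 to 18867895 (+). BomS3 (FBgn0040736) lies on 2R at 18387895 to 18388734 (+) and Charon (FBgn0031317) on 2L at 1170753 to 1172805 (−). PGRP-SB1 (FBgn0043578) lies on 3L at 16727299 to 16727989 (−), Drsl2 (FBgn0052279) on 3L at 3314349 to 3314681 (+) and LysX (FBgn0004431) on 3L at 1194739 to 1195302 (−). Cyp304a1 (FBgn0038095) lies on 3R at 12963791 to 12965923 (+), eloF (FBgn0037762) on 3R at 9814161 to 9815158 (+) and Npc2e (FBgn0051410) on 3R at 10053332 to 10054348 (+). Of 153 genes examined, 9 have exons that overlap another gene on the same strand, among them Tat, trh, osk, VAChT and Argl, and 33 overlap only a gene on the opposite strand, among them Charon, Lsp2, Mal-A1, tobi, Npc2e, DptB, PGRP-SD and LysD. The strandedness of the libraries is not given in the sources used here, so reads of these genes and their partners may not have been told apart.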

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

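The comparisons with other splits of the libraries and the control splits were set before their results were seen. So were the depth tests, except that of HSD against CD. The test of out-of-place libraries in day 50 sons had its bar set beforehand, but which libraries it leaves out was chosen after seeing the data. The other tests in this part were chosen only afterwards.

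Day 10 daughters of HSD and HFD mothers differed in 6867 genes, with muscle and oxidative phosphorylation lower and ovarian germline and cell cycle genes higher in HSD. Without f21, f22, f26 and f27, which age markers and similarity over all genes both place at another day, 2928 of these genes were still called, which argues against those 4 libraries as the whole source. Library f28, nearest to day 50 by age markers alone, stayed in. The age markers include the muscle list, so the placement of these libraries is not independent of their muscle values. Thinning all libraries to the smallest total kept 94.6% of the calls, which argues against unequal depth. A higher share of ovary RNA stays open. It would lower muscle and gut transcripts alike, and the muscle minus gut protease score was 1.25 ± 0.41 in HSD and 4.90 ± 3.68 in HFD (exact permutation p = 0.00794). However, that difference of 3.65 is no larger than the spread in HFD, where f21 and f22 had 9.10 and 8.74 and the others 2.48 at most. With the gonad score as a covariate 902 genes were called, 876 of them among the 6867. The mean log2 CPM over the ovarian germline list was 6.41 or more in HSD and 6.17 at most in HFD. With the groups apart on this list, that fit cannot tell a share of ovary RNA from maternal diet. A response to the maternal diets and a difference in maturation between the groups stay open as well. All are hypotheses that may apply together.

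Of the sugar digestion and transport genes, 10 of 17 fell in day 50 daughters of HFD and 8 of 17 in those of HSD mothers, and 394 genes were lower in both. Chance values of single shared CD libraries are argued against by 71 genes, the lowest number called lower in both when the diets met different CD libraries, against 0 at most in simulations of unchanged groups. That bar is low, since unchanged groups are rarely called. An offset common to all CD libraries would survive the splits. It would also go with the 0 edgeR calls between HSD and HFD, so it stays open. A smaller share of gut would lower lysozymes with the sugar digestion genes. In HSD the difference of the 2 scores was higher than in CD by 2.35, with the groups apart (exact permutation p = 0.0159). The 2 lists were set against each other after results were seen, so this p does not bear on chance. A smaller share of gut therefore stays open in HSD. The lysozymes did not move alike, since LysX fell to 0.09 ± 0.18 from 39.1 ± 26.2 CPM. The calls on the rises of LysD and LysB were lost without f31, f34, f43 or f44 (adjusted p up to 0.0626) and without f31, f32, f33, f34, f41, f43 or f44 (adjusted p up to 0.12), and reads may be shared between them. In HFD the difference was higher by 1.83 (exact permutation p = 0.0159), the groups overlap, and a smaller share of gut stays open there too. Thinning kept 91.6% of the HFD calls, which argues against depth there. It kept 89.5% of the HSD calls, just under the bar of 90%. At equal depth 930 genes were called in HSD, 860 of them among the 961. This argues against depth for those 860, and a part from depth stays open for the rest. An effect of maternal diet on gene use within the aged gut is a candidate explanation, untested here, and a change in 1 gut region alone was not examined. Some falls ran opposite to ageing: Drsl2, PGRP-SB1, LysX and Cyp304a1 rose from day 10 to day 50 in CD daughters and were lower in HSD than in CD. The same CD day 50 libraries enter both comparisons with opposite sign. Genes high in those libraries therefore tend to run opposite without any link to ageing. All day 50 daughters lay nearest to day 50 by age markers. How many called genes ran opposite to ageing was not counted, and the relation was not tested.

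Testis transcripts were higher in day 50 sons of HFD than of CD mothers, although no gene passed over all genes tested. The list also did not pass camera with an estimated correlation. Without m39, m40 and m45 the comparison had 507 calls with 2 HFD libraries left, which goes with the idea that libraries out of place hid a difference. However, without m39 alone it had 0, and fits that kept all libraries had 2365 (other samples in the fit) and 2429 (DESeq2), so that explanation stays open. The exact permutation test of the testis score (p = 0.0357, the smallest possible here) does not bear on chance, because the list was picked after it stood out. Younger flies under a day 50 label stay open. On the ribosomal list HFD sons lie 92.4% of the way from CD day 10 to CD day 50 and on the antimicrobial peptides 75.5%, but on the testis list 18.6% and on the immune recognition list 58.5%. Over all genes m36, m38 and m39 correlate with day 10 sons at 0.968, 0.971 and 0.966 and with day 50 sons at 0.942, 0.921 and 0.936. With 3 HFD libraries, an effect of maternal diet on the ageing testis may be followed up only as a hypothesis.

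Single libraries lay apart from the others of their group in 16 of 100 tests over 20 groups, where chance would give about 5, or 1 in 20 groups per test. In mean log2 CPM over antimicrobial peptides, s6 had 3.93 (others of its group 0.59 to 1.54), m18 had 4.96 (1.25 to 1.52), m27 had 5.68 (1.33 to 1.75), m45 had 0.51 (4.42 to 6.43) and f29 had 2.54 (0.03 to 0.59). Over ovarian germline genes, s2 had 6.73 (6.89 to 6.95), f19 had 5.94 (6.48 to 6.67), f22 had 3.59 (5.83 to 6.17) and f29 had 6.41 (7.04 to 7.16). Over muscle genes, m8 had 6.29 (10.71 to 11.23), m19 had 8.71 (8.46 to 8.53) and m45 had 11.09 (7.91 to 8.22). Over testis genes, m8 had −2.14 (7.14 to 7.21) and m27 had 2.83 (6.78 to 7.28). Over gut serine proteases, m11 had 5.07 (4.31 to 4.52) and m45 had 1.16 (3.72 to 4.51).

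The effect of maternal diet differed between the sexes, by a test of the difference, for 1 gene at day 10 under HFD, 26 at day 50 under HFD and 14 at day 50 under HSD, and between days in daughters for 5275 genes. Of 30 drawn splits of the libraries, 5 gave 1 call or more at day 10 under HFD, the real one included, with 43 as the highest other, so chance is not excluded there. Only the real split, 1 of 30, gave 26, 14 and 5275, with 0, 0 and 7 as the highest others.

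For the comparisons within a sex and day, only the real split, 1 of 50 drawn, gave as many calls as observed in day 10 daughters for HFD against CD (5, highest other 0) and HSD against HFD (6867, highest other 2886). The same held in day 50 daughters for HFD against CD (632, highest other 61) and HSD against CD (961, highest other 3), and in ageing (7504, 4863, 3521 and 8310, highest others 7314, 0, 133 and 2). A share of 1 in 50 argues against chance for each taken alone but does not exclude it. Over the 33 comparisons together it argues less. Libraries of a group may share a culture, and these splits cannot tell a difference between cultures from one between the groups compared. The 5 calls became 0 without f16, f17, f18, f20, f22, f23, f24 or f25 and 623 and 413 without f19 and f21. The 7314 calls of another split lie close to 7504, so part of that count may go with a structure other than age. Where edgeR called 0 genes, all 50 of 50 splits are as large by construction, which says nothing about chance. The highest others, in the order HFD against CD, HSD against CD and HSD against HFD, were 0, 208 and 1339 in mothers and 0, 2 and 6348 in day 0 daughters. They were 3 in day 10 daughters for HSD against CD and 664 in day 50 daughters for HSD against HFD. They were 1, 0 and 1 in day 0 sons, 0, 215 and 0 in day 10 sons and 0, 0 and 116 in day 50 sons. For the other sex differences and the day dependence in sons, with 0 calls, 30 of 30 splits are likewise as large by construction, with highest others of 2065 and 1 at day 0 under HFD and HSD, 4 at day 10 under HSD and 261 in sons. EdgeR's counts at an unadjusted p under 0.05 and those of DESeq2 are in the results above. Splits that call many genes, such as 6348, where the real split calls few point to a structure of the samples other than maternal diet.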

How the results depend on the processing

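The fits without libraries placed at another sex or day (the latter by age markers and by similarity over all genes), without libraries holding transcripts of the other sex and with the gonad score were chosen only after the data were seen, the first of them after other versions were tried. Age markers are part of what was measured, so that fit is not a cleaner version of the comparison. No paired analysis was made. Library numbers run on through the groups of each sex, so none is shared between diets within a sex. Many numbers recur between sons and daughters of the same diet and day, but the labels name no pairing. The causes of the changes below were not tested.

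DESeq2 gave 15, 38 and 1 calls in mothers (HFD against CD, HSD against CD, HSD against HFD), 147 in day 0 daughters for HSD against HFD, and 1, 5 and 2 in day 0 sons. It gave 928 and 241 in day 10 daughters against CD, 3, 20 and 46 in day 10 sons, 1451 and 333 in day 50 daughters for HSD against CD and HFD, and 2429, 29 and 14 in day 50 sons. It gave 206, 575, 280, 10, 485 and 160 for the sex differences (HFD then HSD at days 0, 10 and 50) and 81 for day dependence in sons. Shared calls by DESeq2 were 1 between diets in mothers, 2 in day 10 daughters (42 opposite) and 23 in day 50 sons, 1, 197 (10 opposite) and 3 between sexes (day 10 HSD, day 50 HFD and HSD) and 6 and 9 (2 opposite) between mothers and day 50 daughters (HFD, HSD), where edgeR shared 0. At an adjusted p under 0.1 the sexes shared 109 under HFD at day 50 (6 opposite). Other samples in the fit gave 2 and 471 in day 0 daughters (HSD against CD and HFD), 404 and 1 in day 10 and 359 and 268 in day 50 daughters against CD. They gave 3 and 1042 in day 0 sons (HFD against CD, HSD against HFD), 2365, 2 and 1 in day 50 sons. They gave 191, 4 and 6 for the sex differences (HSD day 0, HFD days 10 and 50), 2918 for daughters from day 10 to 50, 1880 for sons from day 0 to 10 and 994 for day dependence in sons. Without a count filter the sex difference under HSD at day 50 had 8 calls.

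Without libraries placed at another sex or day, day 10 daughters had 582 (HFD against CD) and 3277 calls (HSD against HFD), day 10 sons 1, 7 and 48, and day 50 sons 507 and 10 (HFD against CD, HSD against HFD). The sex differences had 479 at day 10 under HFD and 457 and 149 at day 50, and day dependence in sons 2066. With the gonad score there were 5 and 3 in mothers against CD, 0, 1 and 902 in day 10 daughters, 1, 2 and 68 in day 10 sons and 1224, 2142 and 341 in day 50 daughters, of which 43.2, 42.3 and 25.2% were higher (10.9 and 30.8% against CD without the score). Without libraries holding transcripts of the other sex, 12 of 12 counts stayed within 1.5 times, as did 33 of 33 with median-of-ratios size factors. That scaling shifted the median of all genes by more than 0.1 only for the sex difference under HSD at day 0.

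Leaving out each library gave 0 to 623, 0 to 1350 and 5738 to 7407 calls in day 10 daughters, 407 to 912, 399 to 899 and 0 to 326 in day 50 daughters. It gave 0 to 3, 0 to 1 and 0 to 1 in day 0 sons, 0 to 0, 0 to 7 and 0 to 48 in day 10 sons and 0 to 0, 0 to 1 and 0 to 0 in day 50 sons, and 0 to 0 in mothers and day 0 daughters. Sex differences ranged over 0 to 0 at day 0, 0 to 344 and 0 to 307 at day 10 and 1 to 176 and 1 to 91 at day 50. Ageing ranged over 6969 to 7833 and 3822 to 5731 in daughters and 3056 to 3510 and 7713 to 8091 in sons, and day dependence over 3339 to 6796 in daughters and 0 to 22 in sons. Of 165 called values of named genes, 120 stayed called under each planned setting and 127 without each library. Signs turned for 4 genes that were not called, all under HFD. They were sro in day 50 daughters (−0.01, −0.00 and −0.10 without f33, f35 and f38; range −0.10 to 0.35), Tat and Hpd in day 10 sons (0.00 and 0.01 without m23; ranges −0.10 to 0.00 and −0.16 to 0.01) and Cyp309a1 in day 50 sons (0.47 with the gonad score, 0.07 and 0.12 without m31 and m38; range −0.45 to 0.12). Simulated changes of 2 times were recovered for 80.6% of genes in day 50 daughters and for 7.46% in day 50 sons under HFD, so low counts in sons do not show that sons did not respond.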

Other observations

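All lists in this part were planned and no test was added after a result was seen. In day 50 daughters of HSD mothers (n = 4) against CD (n = 5), odorant binding and chemosensory genes rose in 15 and fell in 2 of 38. Without f43, 9 were called. There were 22 higher and 7 lower when adjusted over the list alone (adjusted p = 2.32e-07; adjusted p = 0.419 with an estimated correlation). Obp56g rose to 10.7 ± 1.86 from 2.93 ± 1.18 CPM (adjusted p = 0.0147), a call lost in a fit over all 9 groups of daughters (adjusted p = 0.219). Cuticle proteins rose in 4 of 21, likewise 4 when adjusted over the list alone, with Cpr72Ec at 11.4 ± 1.85 against 1.81 ± 1.04 CPM (list adjusted p = 1.95e-05; adjusted p = 0.305 with an estimated correlation). Muscle genes rose in 5 of 22, 8 when adjusted over the list alone, with sls at 615 ± 157 against 336 ± 43.6 CPM (list adjusted p = 1.36e-06; adjusted p = 0.419 with an estimated correlation). The call on sls was lost without f31, f41 or f43 (adjusted p up to 0.0757) and in that wider fit (adjusted p = 0.16). The 5 muscle calls became 2, 3, 3, 2, 2 and 3 without f31, f34, f35, f41, f43 and f44, and the 4 cuticle calls 2 without f31, f33, f35, f41, f43 or f44. Yolk proteins had a median of −0.83, with 3 of 4 lower when adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.419 with an estimated correlation). Yp3 was 2780 ± 1000 against 6860 ± 2320 CPM (adjusted p = 0.0364), a call lost without f31, f32, f34, f35, f41, f42 or f44 (adjusted p up to 0.11) and in the wider fit (adjusted p = 0.503).

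Ageing and day 10 held further groups. Neuronal genes fell in 29 of 29 in CD daughters from day 0 to day 10, with a median of −1.51 (adjusted p = 6.84e-12; adjusted p = 0.597 with an estimated correlation). Antimicrobial peptides rose in 16 of 20 and fell in 1 in CD sons over the same days, with a median of 3.23 (adjusted p = 0.0031; adjusted p = 0.581 with an estimated correlation), and 11 were called without m18. Drsl5 rose to 137 ± 27.5 from 19.5 ± 3.44 CPM. In CD daughters 9 of 19 rose and 4 fell (adjusted p = 0.317). Among them Def rose to 59.4 ± 22.4 from 12.4 ± 5.2 CPM (adjusted p = 7.11e-05) and DptA to 23.9 ± 32.7 from 1.24 ± 0.733 CPM (adjusted p = 0.00303), while Drsl2 fell to 1.03 ± 0.461 from 9.77 ± 11.9 CPM (adjusted p = 4.71e-04). Between HSD and HFD daughters at day 10, cytochrome P450s fell in 56 of 80 and rose in 6 (adjusted p = 4.95e-07; adjusted p = 0.585 with an estimated correlation), with Cyp318a1 at 1.69 ± 0.881 against 8.74 ± 0.744 CPM. Gluconeogenesis, trehalose and glycogen genes fell in 9 of 10 (adjusted p = 8.11e-04; adjusted p = 0.585 with an estimated correlation).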
